A study of Mus musculus with 4 samples.

How the data were processed

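Circular RNAs (circRNAs) are covalently closed transcripts in which a downstream splice site is joined to an upstream one. Their abundance was measured by RNA sequencing in mouse brain tissue. Per the labels, RNA was extracted with Trizol after cardiac perfusion, ribosomal RNA was removed and directional libraries were made; the labels name both a TruSeq kit and a NEBNext kit for this. The sources used here give 4 libraries. In 3 of them the tissue came from mice 3 h after permanent middle cerebral artery occlusion (MCAO), a model of ischemic stroke in which a filament closes the artery, and the RNA of 6 mice was pooled for each. These 3 libraries are the infarct core near the frontal lobe (core frontal), the infarct core near the occipital lobe (core occipital) and the penumbra, the tissue around the core that is short of blood but not yet lost. The library from sham mice is the control. The number of sham mice and the time of their sampling are not given in the sources used here.

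Each library was placed in its group by its tissue or treatment label, and each column of the tables was matched to its library by the column name in that library's labels. There was 1 library per group, so no value has a replicate error. Pooling averages over mice and removes the spread between them from view.

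The deposited count table holds whole-number read counts for 23980 circRNAs, without normalization, identified by chromosome, start and end. The authors listed TopHat2 2.0.10 and Bowtie and the build mm9, per the submitters' processing notes. The program that called circRNAs and the annotation are not given in the sources used here. Each circRNA in the table has a sum of at least 2 counts over the 4 libraries. The deposited FPKM table (fragments per kilobase of span, scaled to the library total) holds the same circRNAs. Its values equalled the count divided by the genomic span and by the library's total circRNA count, to a largest relative difference of 5.11e-15. The span includes introns, with a median of 12557 bases, while the median spliced length was 541 bases. FPKM values therefore add no information on a single circRNA beyond the counts, and their levels cannot be compared between circRNAs. Counts scaled to the library's total circRNA count, in CPM, were used here.

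The build was settled from the coordinates, because the processing notes and the table differ. The coordinates fit GRCm38: 89.1% of starts and 89.7% of ends lay exactly on exon boundaries of GENCODE M21, compared with 0.192% of starts when moved by 1 base. All coordinates are given as deposited, 1-based, on GRCm38. The table gives neither strand nor gene names. A host gene was assigned where both ends, or 1 end alone, lay on an exon boundary of a gene or, with neither end on a boundary, where the circRNA lay inside a gene. No host was given where the ends lay on boundaries of different genes. This gave a host for 23463 circRNAs (97.8%) in 5427 genes. Both ends lay on exon boundaries of the same gene for 19904 circRNAs (83.0%), and 2883 (12.0%) had 1 end on a boundary. Protein-coding genes were preferred among candidates, and more than 1 candidate remained for 176 circRNAs. Exons are numbered in transcription order along the transcript with the most exons among those that contain both ends. Without strand in the table, the strand is that of the host, and overlapping genes on opposite strands cannot be told apart. A spliced sequence, and so a GC content, could be derived for 19586 circRNAs (81.7%).

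The total circRNA count was 121393 in core frontal, 83090 in core occipital, 96349 in penumbra and 106558 in sham. Each CPM carries a 95% Poisson interval and each ratio a 95% exact conditional (Clopper-Pearson) interval. These intervals cover counting error only, and PCR reads without molecular identifiers are not independent molecules. The floor of 3 counts corresponds to 24.7 CPM in core frontal, 36.1 in core occipital, 31.1 in penumbra and 28.2 in sham. A library with a count of 0 was set to this floor of 3 counts for a ratio, which is then given as a bound. Counts of 1 to 3 were used as they are, although the wording fixed beforehand can also be read as raising counts under 3 to 3.

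All 6 pairs of libraries were compared. For each circRNA with 10 or more counts over the 2 libraries, Fisher's exact test (two-sided) set its count against the rest of each library's circRNA count, with Benjamini-Hochberg adjustment over the circRNAs tested. A circRNA was called at an adjusted p under 0.05 and a CPM ratio of at least 2. Such a test compares those libraries, not the conditions. For each pair, 100 pairs of libraries drawn from a common pool gave the number of calls from counting error alone. For circRNAs with 100 or more counts over the 2 libraries, the first library's count was compared with the share expected from the totals. Its squared deviation was divided by the binomial variance that counting error gives, and averaged. The percent variation beyond counting error was taken from the variance of their log ratios in excess of counting error, and is given per library. For each library, circRNAs called higher than in each of the other 3 were sought. Overlaps of calls between comparisons that share the sham library were set against 100 simulated libraries without any difference.

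The tests and thresholds, the alternatives, the rule for the named circRNAs and 18 lists of host genes were fixed before the data were examined, apart from the additions named as such. The lists cover circRNA hosts from stroke studies, abundant brain circRNA hosts, glutamate synapse, ion channel and calcium, mitochondria and energy metabolism, ubiquitin and protein turnover, chromatin and transcription, small GTPase and cytoskeleton, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia and leukocyte, endothelial and mural, interneuron, striatal, cortical excitatory, hippocampus and thalamus, and immediate early and stress genes. Some genes, such as Homer1, Ogdh, Slc8a1 and Cdyl, stand in several lists, and brain tissue expresses the genes of all of them. For a list, the median log2 ratio of its circRNAs tested was placed as a percentile among 10000 random lists of the same size matched on mean level in 10 bins, as a description of these libraries. Lists with fewer than 5 circRNAs tested got no percentile. The counts of all circRNAs of a list were also summed.

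The circRNAs named are, for each comparison, up to 10 called higher and up to 10 called lower with the largest ratios, up to 4 called members of each list, every circRNA tested of the Ogdh locus, the most abundant circRNA of Rims2, Hipk3, Homer1, Dlgap4 and Tlk1, and the 5 most abundant circRNAs in each library. Those hosted by Cdr1 and Cdr1os, also under the rule, were not analysed here, and some other circRNAs under the rule are not reported here, although they stay in every test and count. Host genes named from sums over all their circRNAs, Ptk2 beside the penumbra comparison with sham, and the small RNA genes other than Snora61 and Snord118 named at the end were chosen after their values were seen. The ratio of Ssbp2 between penumbra and core occipital was also picked out after values were seen.

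The alternatives were TMM factors and DESeq2 size factors in place of library totals, no filter and a filter of 30 counts, no minimum ratio, and edgeR's exact test at an assumed coefficient of variation of 0.2. Another was edgeR's quasi-likelihood test with the 2 core libraries taken as replicates, which assumes that penumbra and sham vary like them. It joins the cores into a single group, so a comparison with either core is a comparison with both together. Its versions for core frontal and for core occipital differ only in the circRNAs included, and a difference in a single core is averaged with the other. Detection was repeated with a minimum of 2 counts and with each library thinned to the smallest total. Chosen after seeing the data were removal of the GC trend in 10 bins (an exact binomial test against the ratio of the bin, with no correction for circRNAs without a spliced sequence), restriction to circRNAs with both ends on exon boundaries of the same gene, counts summed per host gene, and a pseudocount of 0.5 for the lists.

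The scripts were tested on simulated data drawn from the real means and library sizes with 200 changed circRNAs. Of the 4-fold changes among circRNAs tested, 45.9% were called for penumbra against sham, 44.9% for core frontal against sham, 49.0% for core occipital against sham, 46.5% for penumbra against core frontal, 51.1% for penumbra against core occipital and 45.4% for core frontal against core occipital. Of the 2-fold changes, 15.1%, 9.78%, 9.47%, 20.2%, 11.1% and 6.52% were called in the same order. Between 0 and 5 unchanged circRNAs were called per comparison. The 2-fold changes included between 6 and 11 circRNAs with 100 or more expected counts per comparison. Between 71.4% and 100% of these had an adjusted p under 0.05, so in the simulation the limit lay mainly with circRNAs of few counts. The simulated libraries held counting error only, while the real ones varied beyond it. These shares and false calls therefore do not carry over to the real libraries.

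Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used. Linear transcripts of the host genes were not analysed here, so a difference in a circRNA cannot be set against one in its gene.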

Results

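The circRNAs of 4 mouse brain libraries were compared: the frontal and the occipital part of the infarct core, the penumbra and sham. There are no replicates, so every difference below is between 2 libraries of pooled RNA and cannot be separated from variation between pools. Ratios are given with their 95% interval in square brackets, and coordinates are on GRCm38. Where a library had 0 counts, the fold given as "at least" is that with 3 counts in their place, and the limit of the 95% interval nearest to 1 follows it.

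The most abundant circRNA in all 4 libraries was one of Tulp4 (17:6137211-6139156, including an untranslated exon) at 9918 CPM in core frontal, 9532 in core occipital, 8874 in penumbra and 9244 in sham. The others among the 5 most abundant of at least 1 library were Ssbp2 exons 2 to 4 (13:91524585-91564694; 925, 500, 762 and 885 counts in the same order), Gigyf2 exons 4 to 8 (1:87364104-87380008; 864, 589, 737 and 887) and exon 2 of Fat3 with its untranslated part (9:16374949-16378254; 686, 503, 544 and 479), a giant cadherin, with Slc8a1, Rims1 and Med13l. Exon 2 of Slc8a1, the sodium-calcium exchanger (17:81647809-81649638), had 628, 442, 452 and 420 counts. Rims1 (1:22346293-22393948), of the presynaptic active zone, had 571, 450, 445 and 503. Exon 2 of Med13l (5:118593333-118593570) had 516, 426, 451 and 578. The 10 most abundant circRNAs held 5.72% of the counts in core frontal, 5.62% in core occipital and 5.66% in sham.

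Of the 23980 circRNAs, 16611 were detected in core frontal, 15921 in core occipital, 16570 in penumbra and 16226 in sham. Thinned to the total of the occipital library, these were 14725, 15921, 15680 and 14897. All 4 libraries detected 7284 of them (30.4%), and 6736 (28.1%) had 10 or more counts over the 4 libraries. Counts on circRNAs with both ends on exon boundaries of the same gene made up 90.8% of the total in core frontal, 90.6% in core occipital, 90.7% in penumbra and 90.7% in sham.

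**Figure D1:**
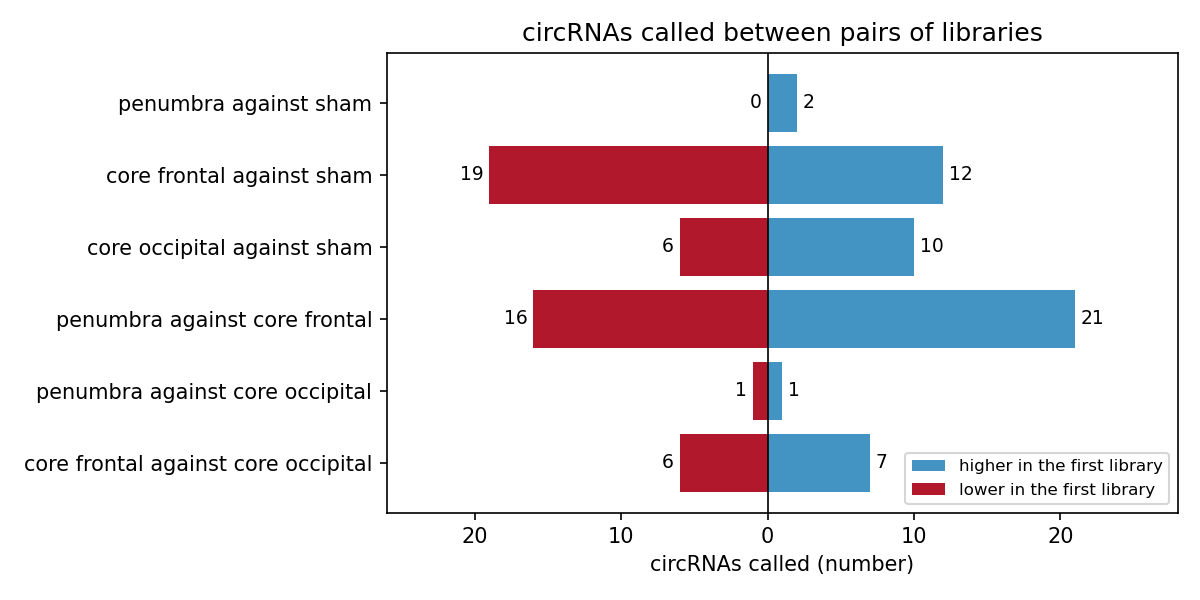
Number of circRNAs called higher and lower in the first library of each of the 6 comparisons (adjusted p under 0.05 and a CPM ratio of at least 2, 1 library per group).

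In the penumbra, 2 circRNAs were called higher than in sham and 0 lower, of 3717 tested. The first joins exons 11 to 13 of Atp2b2, a plasma membrane calcium pump (6:113789753-113796397), with 78 counts in penumbra and 34 in sham, a ratio of 2.54 [1.68–3.92] (adjusted p = 0.00478). Its CPM was 810 in penumbra, 638 in core occipital, 568 in core frontal and 319 in sham. The second is a junction at Gm47283 (Y:90739142-90793417, 1 end on an exon boundary) with 44 and 7 counts, 6.95 [3.11–18.3] (adjusted p = 3.58e-05). Its gene lies near the part of chromosome Y shared with X, and its counts may not be assignable to Y. The only other circRNA at an adjusted p under 0.05, named after values were seen, is a circRNA of Ptk2, the focal adhesion kinase (15:73391759-73394744), with 170 counts in penumbra and 286 in sham, 0.657 [0.541–0.798] (adjusted p = 0.0148), a difference under the 2-fold rule. The ratio of Atp2b2 with the GC trend removed was 2.16 (adjusted p = 0.0594) and it was no longer called. At 30 counts 5 were called higher and 3 lower. In simulated pairs without a difference the highest number of calls was 1. edgeR's quasi-likelihood test, with both cores as replicates, called 0 circRNAs (124 at an unadjusted p under 0.05), and edgeR's exact test at an assumed coefficient of variation of 0.2 also 0 (155), against 421 by Fisher's test.

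Of Ogdh, a subunit of oxoglutarate dehydrogenase in the citric acid cycle, 3 circRNAs were tested and none was called in any comparison. The junction of exons 3 and 4 (11:6313788-6317080) had 36 counts in core frontal, 28 in core occipital, 48 in penumbra and 44 in sham. The ratio of penumbra to sham was 1.21 [0.785–1.86] (adjusted p = 0.825), to core frontal 1.68 [1.07–2.66] (adjusted p = 0.257) and to core occipital 1.48 [0.909–2.45] (adjusted p = 0.827). At the same locus, 11:6311009-6317080 had 22, 15, 25 and 28 counts (penumbra to sham 0.987 [0.552–1.76]), and exons 3 to 5 (11:6313788-6324922) had 16, 7, 7 and 23 (0.337 [0.122–0.810], adjusted p = 0.245).

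Other circRNAs known from brain or stroke studies were also not called wherever they were tested. In the order core frontal, core occipital, penumbra and sham, exon 2 of Hipk3 (2:104470749-104471847) had 217, 190, 216 and 202 counts and Homer1 exons 2 to 5, from a scaffold of the postsynaptic density (13:93341756-93356079), had 233, 168, 189 and 223. Tlk1 (2:70770004-70786995) had 267, 211, 248 and 297, and Dlgap4 (2:156745835-156749356) had 2, 9, 3 and 6, too few to be tested in penumbra or core frontal against sham and in penumbra against core frontal. Rims2 (15:39566943-39616510) had 252, 222, 246 and 302, with a ratio of core frontal to sham of 0.732 [0.617–0.869] (adjusted p = 0.0425), under the 2-fold rule.

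**Figure D2:**
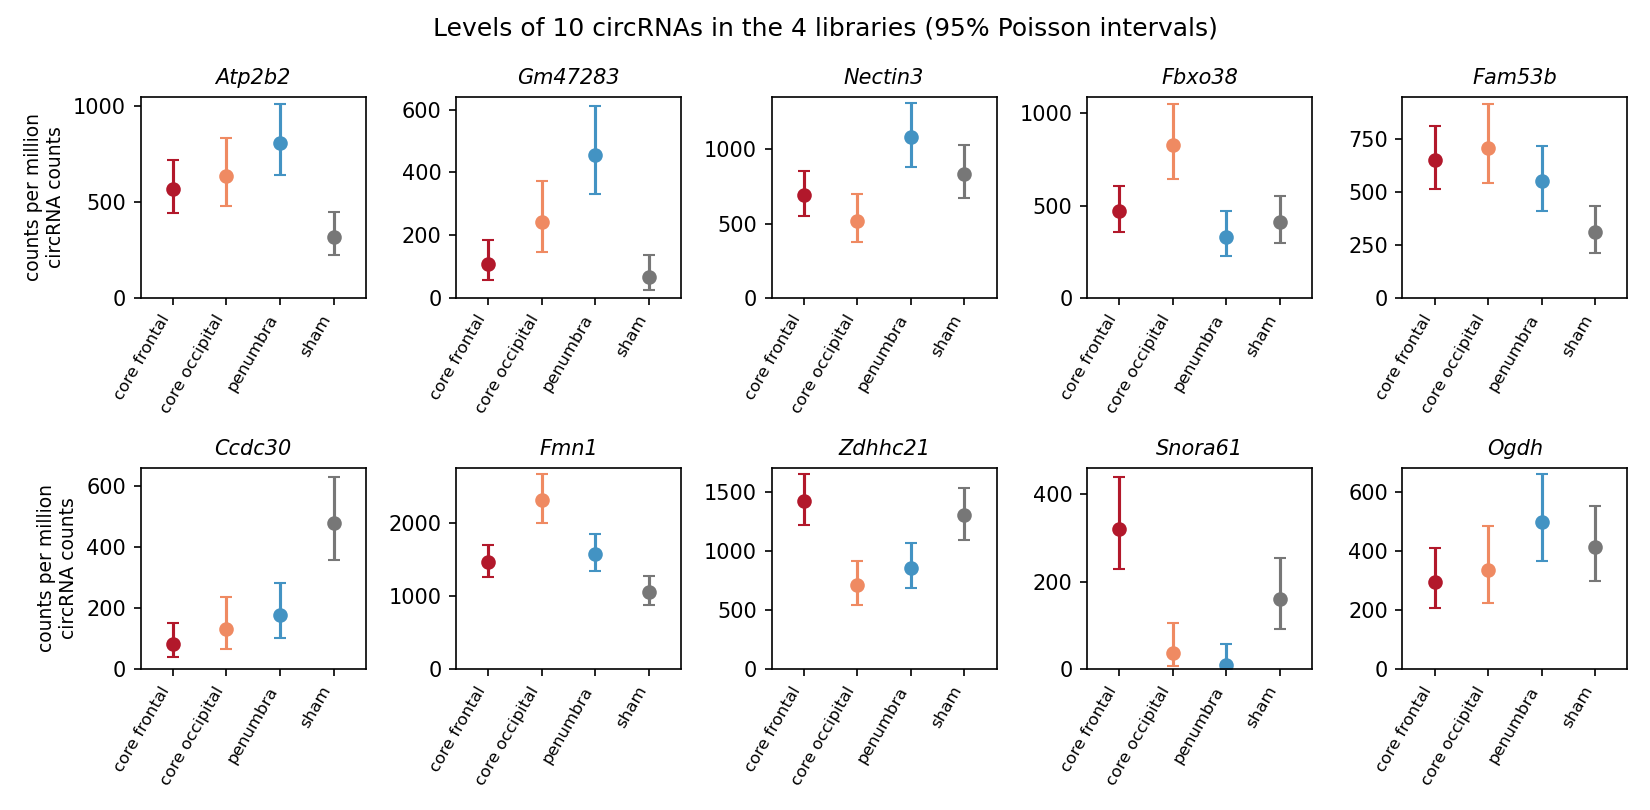
CPM of 10 circRNAs in the 4 libraries with 95% Poisson intervals, which cover counting error only.

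In core frontal, 12 circRNAs were called higher and 19 lower than in sham, of 4152 tested. Among those higher were Grip1 exons 17 to 19, from a scaffold of AMPA receptors (10:120035351-120038793; 25 and 4 counts, 5.49 [1.89–21.7], adjusted p = 0.0425), Ppp1r9a exons 10 to 12, from an actin-binding protein of neurons (6:5113601-5115480; 31 and 6, 4.54 [1.86–13.3], adjusted p = 0.0423), Epb41l3 exons 2 and 3 (17:69207859-69210383; 81 and 30, 2.37 [1.54–3.73], adjusted p = 0.0124) and Epb41l1 exons 11 to 15 (2:156508813-156514210; 76 and 32, 2.08 [1.36–3.26], adjusted p = 0.0427). Fam53b exons 2 to 4 (7:132759389-132779385) had 79 and 33 counts, 2.10 [1.38–3.26] (adjusted p = 0.0425). Ash1l, a histone methyltransferase (3:88965812-88985790; 38 and 10), was higher by 3.34 [1.63–7.51], Dpy19l1 (9:24462577-24485729; 42 and 10) by 3.69 [1.82–8.24] and Arel1 (12:84934152-84951381; 24 and 4) by 5.27 [1.81–20.9] (adjusted p = 0.0492, and 0.0511 with DESeq2 size factors, where it was not called). Fryl (5:73069883-73072921) and the vault protein gene Mvp (7:126998226-127001958) each had 13 and 0 counts, at least 3.80-fold (interval limit 2.68).

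Lower in core frontal than in sham were Ccdc30 (4:119339761-119340684, 1 end on an exon boundary; 10 and 51 counts, 0.172 [0.0779–0.343], adjusted p = 1.42e-05) and Ambra1 exons 11 and 12, from a regulator of autophagy (2:91824460-91825352; 1 and 22, lower by 25.1-fold [4.05–1034], adjusted p = 0.00135). Dapk1, a death-associated kinase (13:60762357-60762518; 6 and 28), was lower by 5.32-fold [2.16–15.7] (adjusted p = 0.0170), the protease Adam10 (9:70703287-70748266; 2 and 17) by 9.68-fold [2.30–86.4] and Nemf (12:69320373-69322350; 3 and 19) by 7.22-fold [2.12–38.1]. Magi2, a synaptic scaffold (5:19999442-20065671; 10 and 31), was lower by 3.53-fold [1.69–8.08] and Kmt2a, a histone methyltransferase (9:44828784-44829271; 38 and 71), by 2.13-fold [1.42–3.24]. The sodium leak channel Nalcn (14:123460237-123515773), Itsn1 (16:91815402-91837188) and the deubiquitinase Usp9x (X:13123168-13124663) each had 0 and 11 counts, at least 4.18-fold lower (interval limit 2.86). Thap4 (1:93714898-93725316) and Vps13d (4:145016735-145020269) each had 0 and 10, at least 3.80-fold lower (interval limit 2.55), and were no longer called with the GC trend removed (adjusted p = 0.0531 and 0.0530) or with DESeq2 size factors (adjusted p = 0.0512 for both). Without the count filter, which adjusts over more circRNAs, 0 were called higher and 4 lower. Simulated pairs gave at most 1 call. edgeR's quasi-likelihood test of both cores together against sham called 0 (190 at an unadjusted p under 0.05). Its exact test of core frontal against sham called 0 (273), against 589 by Fisher's test.

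In core occipital, 10 circRNAs were called higher and 6 lower than in sham, of 3424 tested. The one with the smallest p was exon 2 of Fmn1, a formin that nucleates actin (2:113363836-113365829), with 192 and 113 counts, 2.18 [1.72–2.77] (adjusted p = 4.54e-08). Kcnh5 exons 4 to 7, from a voltage-gated potassium channel (12:75087405-75131026), had 27 and 4 counts, 8.66 [3.02–34.0] (adjusted p = 0.000804), and Anapc1 exons 3 to 14, from the anaphase-promoting complex (2:128668925-128684663), had 21 and 3, 8.98 [2.68–47.0] (adjusted p = 0.00489). Also higher were C2cd5 (6:143029160-143072694; 29 and 11, 3.38 [1.64–7.50]), Rasgef1b (5:99240823-99243246; 25 and 8, 4.01 [1.75–10.3]), Fam53b (59 and 33, 2.29 [1.47–3.62]), exon 2 of Sel1l3 (5:53199901-53200471; 71 and 44, 2.07 [1.40–3.09]) and Fbxo38 exons 2 to 14 (18:62516964-62541046; 69 and 44, 2.01 [1.36–3.01]). Satb1 (17:51767892-51809287; 62 and 37) was higher by 2.15 [1.41–3.32] and Smarca2, an ATPase of the BAF complex (19:26619684-26640649; 10 and 0), by at least 4.27-fold (interval limit 2.87).

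Lower in core occipital than in sham were Ccdc30 (11 and 51 counts, 0.277 [0.130–0.537], adjusted p = 0.00851), Fam228b (12:4762327-4764147; 36 and 98, 0.471 [0.312–0.697], adjusted p = 0.0186), Tmem56 (3:121228310-121235764; 21 and 63, lower by 2.34-fold [1.41–4.04]), the kinase Map2k4 (11:65756269-65775765; 3 and 26, by 6.76-fold [2.07–34.9]), the deubiquitinase Usp34 (11:23351592-23355098; 1 and 18, by 14.0-fold [2.22–585]) and Lrch2 (X:147484302-147484418; 1 and 20, by 15.6-fold [2.49–646]). With TMM factors, which shift these log2 ratios by -0.11, 5 were called higher and 16 lower, and C2cd5, Rasgef1b, Satb1, Sel1l3 and Fbxo38 were no longer called (ratios of 3.13, 3.71, 1.99, 1.91 and 1.86, adjusted p between 0.0553 and 0.0718); Fbxo38 was also not called with DESeq2 size factors (1.99). With the GC trend removed, 2 higher (Kcnh5 and Anapc1) and 2 lower (Lrch2 and Ccdc30, which have no GC value and were not corrected) stayed called, all 4 lower calls with a GC value ended, and Fmn1 had a ratio of 1.91 (adjusted p = 4.51e-05), under the 2-fold rule. Without the count filter 3 were called higher and 0 lower, and at 30 counts 12 lower. Simulated pairs gave at most 1 call. edgeR's quasi-likelihood test of both cores together against sham called 0 (152 at an unadjusted p under 0.05). Its exact test of core occipital against sham called 0 (164), against 432 by Fisher's test.

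Both cores shared 1 called circRNA in each direction against sham: Fam53b was higher and Ccdc30 lower in both. Fam53b was no longer called in core occipital with the GC trend removed (1.92, adjusted p = 0.146). Independent lists would share 0.0228 and 0.0362 and simulated libraries at most 0, but the former ignore the shared sham library and the latter have too few calls to share, so neither is a reference for this overlap. Fam53b had 651 CPM in core frontal, 710 in core occipital, 550 in penumbra and 310 in sham (penumbra to sham 1.78 [1.13–2.83], adjusted p = 0.245). Ccdc30 had 82.4, 132, 176 and 479 CPM (penumbra lower than sham by 2.71-fold [1.54–5.01], adjusted p = 0.0615). The penumbra shared 0 calls with either core, which its 2 calls against sham leave undecided. The sham library is a single library in all of these comparisons and its own deviation enters each of them.

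Several of the most abundant circRNAs also differed between the cores and sham by less than 2-fold. Fat3 was higher in core frontal (1.26 [1.12–1.42], adjusted p = 0.0393) and core occipital (1.35 [1.19–1.53], adjusted p = 0.00189), as was Slc8a1 (1.31 [1.16–1.49], adjusted p = 0.00813, and 1.35 [1.18–1.55], adjusted p = 0.00489). Ssbp2 was lower in core occipital (0.725 [0.648–0.809], adjusted p = 4.81e-06) and Med13l in core frontal (0.784 [0.695–0.884], adjusted p = 0.0248). These adjusted p from Fisher's test cover counting error only. Beyond it, each library varied by 14.5% for core frontal against sham and 17.4% for core occipital against sham, so ratios this close to 1 may be variation between libraries.

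Between penumbra and core frontal, 21 circRNAs were called higher and 16 lower in penumbra, of 3962 tested. Gm47283 was higher (44 and 13 counts, 4.26 [2.26–8.63], adjusted p = 0.000625), as were exons 3 to 6 of Sel1l3 (5:53181722-53188082; 32 and 9, 4.48 [2.09–10.7], adjusted p = 0.00829), Rasgrf2, an exchange factor of Ras (13:91968947-91972285; 23 and 5, 5.80 [2.16–19.5]), Dennd1b (1:139040000-139144000; 20 and 5, 5.04 [1.84–17.2]) and the lipid kinase Pip5k1b (19:24346237-24360151; 12 and 1, 15.1 [2.24–646]). The DNA primase subunit Prim2 (1:33628395-33630433; 11 and 0) was at least 4.62-fold higher (interval limit 3.16), and Bcl11b, a transcription factor of striatal and deep-layer cortical neurons (12:107989465-107989827; 10 and 0), at least 4.20-fold (interval limit 2.82). The transcription factor Tcf4 (18:69564034-69564684; 18 and 3, 7.56 [2.21–40.1]), Ptk2 (15:73295353-73298245; 14 and 2, 8.82 [2.03–80.0]), Pde4dip (3:97841634-97843714; 12 and 1, 15.1 [2.24–646]) and the G protein subunit Gnai1 (5:18308553-18308825; 20 and 5, 5.04 [1.84–17.2]) were called as well. Their ratios with the GC trend removed were 6.67, 8.56, 13.3 and 4.72, but their adjusted p was between 0.0555 and 0.0785.

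Lower in penumbra than in core frontal were junctions in the small nucleolar RNA genes Snora61 (4:132310240-132310369; 1 and 39 counts, 0.0323 [0.000798–0.191], adjusted p = 1.6e-05) and Snord118 (11:69073437-69073545; 0 and 19, at least 5.03-fold lower with an interval limit of 3.70, adjusted p = 0.0112). Also lower were Relch (1:105691906-105696596; 7 and 40, 0.220 [0.0833–0.497]), Glce, an enzyme of heparan sulfate synthesis (9:62068385-62088519; 7 and 39, by 4.42-fold [1.96–11.7]), Ppp6r2 in its untranslated exons (15:89242160-89246340; 4 and 30, by 5.95-fold [2.10–23.3]) and the kinesin Kif16b (2:142834077-142857427; 4 and 28, by 5.56-fold [1.94–21.8]). Cfap54 (10:92815881-92821131; 1 and 17, by 13.5-fold [2.11–564]), Sacm1l (9:123568924-123579047; 3 and 23, by 6.08-fold [1.84–31.7]), and Rngtt (4:33379369-33404253) and Stk3 (15:34999831-35115645), each with 6 and 33 (by 4.37-fold [1.81–12.7]), were called as well. Removal of the GC trend left ratios of 0.0832, 0.185, 0.257 and 0.257, but their adjusted p was between 0.0674 and 0.0989. Cfap54 and Sacm1l were also not called with TMM factors (adjusted p = 0.0506 and 0.0509). Without the count filter 2 were called higher and 2 lower. Simulated pairs gave at most 2 calls. edgeR's quasi-likelihood test of penumbra against both cores together called 0 (135 at an unadjusted p under 0.05). Its exact test of penumbra against core frontal called 1, lower (218), against 509 by Fisher's test.

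Between penumbra and core occipital, 1 circRNA was called higher and 1 lower in penumbra, of 3301 tested. Exons 6 and 7 of Nectin3, a cell adhesion molecule (16:46436354-46438068), had 104 and 43 counts, 2.09 [1.45–3.05] (adjusted p = 0.0331), with 1079 CPM in penumbra, 835 in sham, 692 in core frontal and 518 in core occipital. Fbxo38, of a ubiquitin ligase, had 32 and 69 counts, 0.400 [0.254–0.617] (adjusted p = 0.0148), with 332, 413, 470 and 830 CPM in the same order. Ssbp2, named by the rule as an abundant circRNA but picked out here after values were seen, was higher by 1.31 [1.17–1.47] (adjusted p = 0.00543), under the 2-fold rule. With TMM factors, a shift of 0.12 in log2, 2 were called higher and 1 lower, and without the count filter 0 in both directions. Simulated pairs gave at most 1 call. edgeR's quasi-likelihood test of penumbra against both cores together called 0 (103 at an unadjusted p under 0.05). Its exact test of penumbra against core occipital called 0 (73), against 232 by Fisher's test.

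The parts of the core also differed: 7 circRNAs were called higher and 6 lower in core frontal than in core occipital, of 3780 tested. Higher in core frontal were exons 2 to 6 of Zdhhc21, a palmitoyltransferase (4:82835446-82854115; 173 and 59 counts, 2.01 [1.49–2.74], adjusted p = 0.00204), Snora61 (39 and 3, 8.90 [2.83–45.0], adjusted p = 0.00204), Ppp6r2 (30 and 3, 6.84 [2.13–35.0]), Rngtt (33 and 4, 5.65 [2.01–21.9]), Cfap54 (10:92815881-92878612; 39 and 5, 5.34 [2.10–17.4]), exons 2 to 18 of Exoc6, of the exocyst (19:37570383-37609105; 36 and 5, 4.93 [1.93–16.1]), and Tmem56 (74 and 21, 2.41 [1.47–4.12]). Among those lower were Bcl11b (0 and 13, at least 6.33-fold with an interval limit of 4.45, adjusted p = 0.00622), Wscd2 (5:113550423-113558463; 53 and 77, 0.471 [0.326–0.677], adjusted p = 0.0106), Eprs, a tRNA synthetase (1:185386246-185397267; 3 and 18, 0.114), Bicral (17:46858436-46858698; 5 and 21, 0.163) and the noncoding Lncpint (6:31139729-31197851; 12 and 30, 0.274 [0.128–0.551]).

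Of the abundant circRNAs, Ssbp2 was higher in core frontal than in core occipital by 1.27 [1.13–1.41] (adjusted p = 0.00898). With TMM factors 14 were called higher and 5 lower, and Wscd2 was no longer called (adjusted p = 0.0231, a ratio just under the 2-fold rule). With the GC trend removed, 1 was called higher (Snora61) and 5 lower, all but Wscd2. Without the count filter 2 were called higher and 1 lower, and at 30 counts 12 higher. Simulated pairs gave at most 1 call. edgeR's exact test called 0 (188 at an unadjusted p under 0.05), against 446 by Fisher's test, and its quasi-likelihood test does not apply to the cores.

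No circRNA was called higher in the penumbra than in each of the other 3 libraries. The number was also 0 for core frontal, core occipital and sham, as was the number of circRNAs called lower in each library than in the other 3.

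The ratios varied by more than counting error. Among circRNAs with 100 or more counts the variance of the counts was 2.65 times that of counting error for penumbra against sham, 3.12 for core frontal against sham, 4.16 for core occipital against sham, 3.08 for penumbra against core frontal, 2.00 for penumbra against core occipital and 3.41 between the cores. The variation beyond counting error, per library and from the log ratios, was 12.6%, 14.5%, 17.4%, 14.8%, 10.2% and 16.4% in the same order. A ratio of 2 libraries varies by more than this. The sources of this variation, such as mice, dissection and library preparation, cannot be separated with 1 library per group.

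In most comparisons the ratios also followed the GC content of the spliced sequence. The mean GC content weighted by counts was 47.6% in core frontal, 48.3% in core occipital, 48.1% in penumbra and 47.7% in sham. The Spearman correlation of log2 ratio with GC content, among circRNAs with 50 or more counts, was 0.313 for penumbra against sham, -0.0628 for core frontal against sham, 0.397 for core occipital against sham, 0.332 for penumbra against core frontal, -0.161 for penumbra against core occipital and -0.439 between the cores. With spliced length the Spearman correlation was 0.0644, 0.246, 0.229, -0.166, -0.253 and -0.0122 in the same order. It was larger in size than that with GC content in core frontal against sham and in penumbra against core occipital. Only the GC trend was removed in the alternatives. CircRNAs are not independent replicates, and no p is given for these values.

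**Figure D3:**
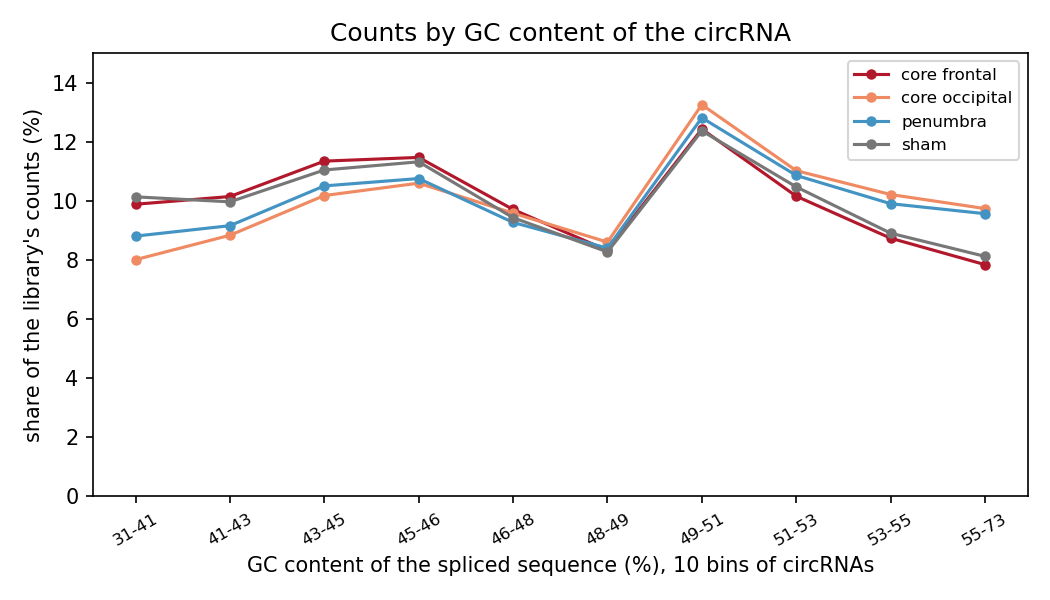
Share of each library's counts in 10 bins of GC content of the spliced sequence, 1 library per group.

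Ion channel and calcium hosts (65 circRNAs tested) had a median log2 ratio of 0.35 in core frontal against sham, at percentile 99.3 of random lists, and a summed ratio of 1.18 [1.12–1.26]. Summed per host gene the median was 0.13 (percentile 87.1). Their sum was also higher in core occipital (1.16 [1.09–1.24]) and penumbra (1.11 [1.05–1.19]), where the medians were 0.11 and 0.15, both inside the central 95% of random lists, and in core occipital -0.0178 (percentile 47.4) when summed per host gene. The list had 21468 CPM in core frontal, 21050 in core occipital, 20218 in penumbra and 18140 in sham. The only call among them is Atp2b2 in penumbra. Adjusted over the list alone, 2 had an adjusted p under 0.05 in penumbra against sham, 1 in core frontal against sham and 2 in core occipital against sham, and 0 in the other comparisons.

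Mitochondria and energy metabolism hosts, among them Ogdh and the carboxylase Acaca, were lower in core occipital than in sham (14 circRNAs tested, median log2 ratio -0.49, percentile 1.87, summed ratio 0.726 [0.629–0.838]; summed per host gene, median -0.23 and percentile 15.4). Astrocyte hosts (0.636 [0.463–0.867]) and endothelial and mural hosts (0.466 [0.219–0.927]) were also lower there. Acsl3, a gene of both the mitochondria and the astrocyte list, held 19 of the 63 astrocyte counts in core occipital and 64 of the 127 in sham. The 2 lists are therefore not separate observations. Acaca held 78 of the 303 mitochondria counts in core occipital and 168 of the 535 in sham. The lower mitochondria sum in core occipital thus rests in large part on Acaca and Acsl3, and the lower astrocyte sum mostly on Acsl3. Neither sum shows a fall shared by the hosts of its list. For mitochondria hosts in core frontal against sham, the sum was 0.801 [0.707–0.907] and the median -0.40 (percentile 2.81). Summed per host gene their median was 0.40 (percentile 98.0), in the opposite direction. In penumbra the median was 0.13 but the sum was 0.854 [0.749–0.972], so the directions differ. Acaca alone held 87 of the 413 counts in penumbra and 168 of the 535 in sham. In penumbra against core frontal the median was 0.49 (percentile 98.7) and the sum 1.07 [0.933–1.22]. At 30 counts the median was 0.25 (percentile 89.3) and summed per host gene 0.42 (percentile 98.75). In penumbra against core occipital the median was 0.34 (percentile 92.9), summed per host gene 0.44 (percentile 99.2), and the sum 1.18 [1.01–1.37]. The list had 0 calls. Adjusted over the list alone, 4 had an adjusted p under 0.05 in penumbra against sham, 2 in core occipital against sham and 0 elsewhere.

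Glutamate synapse hosts had a median log2 ratio of -0.11 between core frontal and core occipital (124 circRNAs tested, percentile 1.77) and a summed ratio of 0.935 [0.896–0.976], with 1 call. The percentile was 7.49 with the GC trend removed and 31.6 when summed per host gene (median -0.0292). Adjusted over the list alone, 2 had an adjusted p under 0.05 there, 2 in core frontal against sham, 4 in core occipital against sham and 0 elsewhere. Small GTPase and cytoskeleton hosts had 0.25 (percentile 97.6) between the cores and a summed ratio of 1.04. The median was 0.0674 (percentile 55.6) at 30 counts and -0.0109 (percentile 40.2) when summed per host gene. Epb41l1 (higher) and Magi2 (lower) were called in core frontal against sham, and adjusted over the list alone, 4 passed between the cores, 2 in core frontal against sham, 2 in penumbra against core occipital and 0 elsewhere. Chromatin and transcription hosts had Ash1l called higher and Kmt2a lower in core frontal against sham, Smarca2 higher in core occipital against sham and Tcf4 higher in penumbra against core frontal. Adjusted over the list alone, 1, 6, 2, 2, 1 and 0 passed in the order of the 6 comparisons above (penumbra, core frontal and core occipital against sham, penumbra against core frontal and core occipital, and between the cores).

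Ubiquitin and protein turnover hosts had Usp9x called lower in core frontal and Usp34 in core occipital against sham, and adjusted over the list alone, 0, 1, 1, 0, 0 and 1 passed in that order. Abundant brain circRNA hosts had 0 calls, and adjusted over the list alone, 3, 10, 5, 0, 0 and 1 passed. CircRNA hosts from stroke studies, 25 of 31 with a circRNA, had 0 calls, and adjusted over the list alone, 0, 1, 1, 0, 0 and 0 passed. Immediate early and stress genes rest on Homer1 alone, as the only host tested, with 0 calls, and adjusted over the list alone, 0, 1, 0, 1, 0 and 1 passed.

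Among cell type markers, astrocyte hosts had 1376 CPM in core frontal, 758 in core occipital, 1183 in penumbra and 1192 in sham. Core occipital was lower than sham (0.636 [0.463–0.867]), core frontal higher than core occipital (1.81 [1.35–2.46]) and penumbra higher than core occipital (1.56 [1.14–2.16]). Acsl3 alone, also in the mitochondria list, held 55 of the 167 astrocyte counts in core frontal, 19 of 63 in core occipital, 35 of 114 in penumbra and 64 of 127 in sham. The lower astrocyte sum in core occipital than in sham therefore rests mostly on Acsl3 and does not show a fall of the other astrocyte hosts. Endothelial and mural hosts had 36, 12, 30 and 33 counts (core occipital to sham 0.466 [0.219–0.927], core frontal to core occipital 2.05 [1.04–4.33], penumbra to core occipital 2.16 [1.07–4.62]). Oligodendrocyte hosts had 1952, 2588, 2398 and 2168 CPM (core frontal to core occipital 0.755 [0.625–0.912]) and oligodendrocyte precursor hosts 1532, 1384, 1702 and 1361 CPM. Microglia and leukocyte hosts had 8, 5, 4 and 10 counts on 3 circRNAs of 1 host. Adjusted over the list alone, 0, 1, 1, 0, 1 and 1 astrocyte circRNAs passed, 1 oligodendrocyte precursor circRNA between the cores, and 0 oligodendrocyte, endothelial or microglia circRNAs in any comparison, with 0 calls in these lists.

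Among neuron and region markers, hippocampus and thalamus hosts had 1204 CPM in penumbra, 989 in core frontal, 867 in core occipital and 666 in sham (penumbra to sham 1.81 [1.33–2.46], core frontal to sham 1.48 [1.10–2.02], penumbra to core occipital 1.39 [1.03–1.89]), with 0 calls. Striatal hosts had 2908, 3189, 2532 and 2590 CPM in core frontal, core occipital, penumbra and sham (core occipital to sham 1.23 [1.04–1.46], penumbra to core occipital 0.794 [0.665–0.948]), while their median log2 ratios there had the opposite sign (-0.10, percentile 38.8, and 0.0291, percentile 39.6). Summed per host gene these medians were 0.67 (percentile 99.0) and -0.32 (percentile 7.19), with the sign of the sums. Between the cores their median log2 ratio was 0.59 (percentile 99.0) but their sum 0.912 [0.775–1.07], in opposite directions, and the median was -0.16 (percentile 13.6) at 30 counts and 0.19 (percentile 79.7) when summed per host gene, with Bcl11b called lower in core frontal than in core occipital and penumbra. Cortical excitatory hosts had 4028, 3972, 4432 and 3988 CPM with 0 calls, and interneuron hosts 1203, 1276, 1142 and 1004 with Grip1 called in core frontal against sham. Adjusted over the list alone, 1 hippocampus and thalamus circRNA passed in penumbra against sham, 0, 0, 1, 1, 0 and 1 striatal, 0 cortical and 0, 1, 0, 2, 0 and 0 interneuron circRNAs passed. Of 76 list percentiles 6 lay outside the central 95%, where 3.8 would by chance if circRNAs were independent. The random lists draw circRNAs singly, while those of a list share hosts, so more than 3.8 may lie there by chance.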

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

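Of the tests below, that of GC content (the number of circRNAs still called) and that of library depth were written before the values were seen. The tests of counting error and of GC content as the whole of the ratios were chosen after the result was seen.

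The parts of the core were each compared with the same sham library, and 13 circRNAs differed between the parts by Fisher's test of their reads, which drew attention to them. Since sham is a single library, its own value decides in part on which side of it each core lies, and the direct comparison of the cores is the test of the difference. Among those higher in core frontal were Ppp6r2 (ratio of core frontal to core occipital 6.84; each core to sham 1.46 and 0.214), Rngtt (5.65; 1.45 and 0.256), Cfap54 (5.34; 2.14 and 0.401), Exoc6 (4.93; 1.22 and 0.247), Tmem56 (2.41; 1.03 and 0.427), Zdhhc21 (2.01; 1.09 and 0.544) and Snora61 (8.90; 2.01 and 0.226). Among those higher in core occipital were Eprs (0.114; 0.527 and 4.62), Bcl11b (0.158 with a core frontal count of 0 set to the floor; 0.439 and 2.78), Bicral (0.163; 0.488 and 2.99), Lncpint (0.274; 0.620 and 2.26) and Wscd2 (0.471; 0.665 and 1.41).

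The 13 calls are more than the at most 1 that counting error gave in simulated pairs of the same totals, but single libraries also vary beyond counting error (3.41 times its variance here), edgeR's exact test at a coefficient of variation of 0.2 left 0 of them, and variation between pools stays open. Thinning both libraries to the same total, after which 12 of 13 kept a ratio of 2 or more, decides nothing about library depth, because it leaves expected shares as they are and the circRNAs were chosen for that ratio. GC content remains a candidate explanation for the calls. With the GC trend removed, 3 of the 10 with a GC value stayed called (Eprs and Snora61 among them), as predicted for a GC effect. Of those lost, 5 ended by an adjusted p of 0.05 or more, Zdhhc21 by a ratio under 2, and Wscd2 by both (adjusted p = 0.164 by the exact binomial test). GC content as the whole of the ratios stays open as well: the interval still excluded 1 in 10 of 10 and the median fold went from 5.13 to 4.60, with expected ratios of the GC bins between 0.807 and 1.24, but these circRNAs were chosen for large ratios, which fixes that outcome in part. Position in the core is the biological explanation the design gives, and without a replicate library it was not tested and stays open. Sums of cell type marker hosts also differed between these libraries. Core frontal to core occipital was 1.81 [1.35–2.46] for astrocyte, 2.05 [1.04–4.33] for endothelial and mural and 0.755 [0.625–0.912] for oligodendrocyte hosts. For oligodendrocyte precursor and microglia hosts the interval held 1. Whether this bears on the calls was not tested.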

How the results depend on the processing

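No paired analysis was possible because there is 1 library per group. Of 78 named calls, 74 stayed called with DESeq2 size factors, 70 with TMM factors, 48 with the GC trend removed (37 of the 67 with a GC value, and the 11 without, which it does not correct) and 13 without a count filter, and all 44 that could be tested stayed called at 30 counts. No named call turned its direction, but that could hardly have come out otherwise. Every call was at least 2-fold, the scalings shift log2 ratios by at most 0.125, and the count filters change only the adjustment of p. Between the cores, the expected ratios of the GC bins lay between 0.807 and 1.24. The counts of calls, detection and the 6 list medians outside the central 95% were followed through the alternatives. They kept their direction and stayed within 1.5 times, or on their side of the percentile limits, in 22 of 22 cases with DESeq2 size factors, 6 of 6 with a pseudocount of 0.5 and 4 of 4 after thinning. The number was 12 of 16 with TMM factors, 7 of 12 with the GC trend removed, 11 of 12 with both ends on exon boundaries and 14 of 22 at 30 counts. It was 10 of 16 without a minimum ratio, 9 of 18 summed per host gene, 6 of 16 without a count filter and 2 of 4 at a minimum of 2 counts. With edgeR's exact test it was 1 of 12 and with its quasi-likelihood test 1 of 10. Part of this tally was fixed in advance. Core occipital was thinned to its own total, and a scaling factor shifts all ratios alike and hardly moves a list percentile. The other list medians were not counted, and some of them moved outside the central 95%. Ubiquitin and protein turnover hosts in core occipital against sham went from percentile 40.8 to 0.45 at 30 counts. Mitochondria hosts in penumbra against core occipital went from 92.9 to 99.2 summed per host gene. The ratio of the FPKM values gives the same ratios as the counts. edgeR's quasi-likelihood test was not run between the cores, its replicates, and a pseudocount for linear genes had no data to apply to. Depth limits detection most in core occipital: at a minimum of 2 counts, 9447 circRNAs were detected there and 10407 in penumbra.

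With TMM factors, 5 were called higher and 16 lower in core occipital against sham, 2 higher in penumbra against core occipital and 14 higher in core frontal against core occipital. With the GC trend removed, 2 were called lower in penumbra against sham, 2 higher and 2 lower in core occipital against sham, 2 higher in penumbra against core occipital and 1 higher in core frontal against core occipital. With a filter of 30 counts, under which fewer circRNAs are tested, 5 were called higher and 3 lower in penumbra against sham, 12 lower in core occipital against sham and 12 higher in core frontal against core occipital, and 1 was called highest in sham. Without a minimum ratio, 1 was lower in penumbra against sham, 14 lower in core occipital against sham, 2 higher in penumbra against core occipital and 12 higher in core frontal against core occipital, and 1 was highest in core frontal and 1 in sham. Without a count filter, under which more circRNAs are tested, the calls were 0 higher and 4 lower in core frontal against sham, 3 and 0 in core occipital against sham, 2 and 2 in penumbra against core frontal, 0 and 0 in penumbra against core occipital and 2 and 1 in core frontal against core occipital. With both ends on exon boundaries of the same gene, 1 was called higher in penumbra against sham, since Gm47283 is left out. With counts summed per host gene, 4 were called higher and 3 lower in penumbra against sham, 3 higher in core frontal against sham and 11 lower in core frontal against core occipital.

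edgeR's exact test at a coefficient of variation of 0.2 called 0 in both directions in all 6 comparisons, except for 1 lower in penumbra against core frontal. edgeR's quasi-likelihood test with both cores as replicates called 0 in both directions in each of its comparisons. Those with a core set both cores together against the other library, so they are not separate checks of each core.

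With a filter of 30 counts the median log2 ratio of striatal hosts between the cores turned from 0.59 to -0.16 (percentile 13.6), that of small GTPase hosts was 0.0674 (percentile 55.6), and that of mitochondria hosts in penumbra against core frontal was 0.25 (percentile 89.3). With sums per host gene, small GTPase hosts turned from 0.25 to -0.0109 (percentile 40.2) between the cores, glutamate synapse hosts had -0.0292 (31.6) and striatal hosts 0.19 (79.7) there, ion channel hosts 0.13 (87.1) in core frontal against sham and mitochondria hosts -0.23 (15.4) in core occipital against sham, all inside the central 95%. With the GC trend removed, glutamate synapse hosts between the cores were also inside it (percentile 7.49). Apart from the number of circRNAs tested, the cause was not tested.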

Other observations

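Of the tests below, that of small RNA yield was written before the values were seen. Both tests of the chromosome Y junctions were chosen after the result was seen, as were the host genes named here.

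Summed over all circRNAs of a host gene, a unit added after seeing the data, 13 hosts had an adjusted p under 0.05 by Fisher's test between penumbra and sham, 33 between core frontal and sham and 45 between core occipital and sham. That test covers counting error only, and neither edgeR nor simulated libraries were run on these sums. Ratios close to 1 may therefore be variation between libraries, whatever their adjusted p. With the GC trend removed the numbers of hosts were 12, 33 and 28, and 10, 30 and 24 stood in both. Counts below are in the order core frontal, core occipital, penumbra and sham, and each host named stood in both. Pcca, a subunit of the mitochondrial propionyl-CoA carboxylase, had 45, 56, 62 and 30 counts, higher than sham in penumbra (2.29 [1.46–3.66]) and core occipital (2.39 [1.51–3.86]). The kinase Vrk2 had 17, 11, 38 and 14 (penumbra to sham 3.00, adjusted p = 0.0496). Acaca, the rate-limiting carboxylase of fatty acid synthesis, had 139, 78, 87 and 168 (penumbra to sham 0.573 [0.437–0.746]), and Eed, of the Polycomb repressive complex, had 41, 27, 15 and 52 (0.319 [0.167–0.575]). The 3 circRNAs of Tcf20, a transcriptional coregulator, had 473, 418, 365 and 309, higher than sham in core frontal (1.34 [1.16–1.56]) and core occipital (1.73 [1.49–2.02], adjusted p = 3.68e-10).

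Further hosts passed in other comparisons, with the same limit. Lrp1b, a receptor of the LDL receptor family, had 296, 143, 142 and 160 counts, higher in core frontal than in sham (1.62 [1.34–1.98], adjusted p = 0.000750) and lower in penumbra than in core frontal (0.604 [0.491–0.741]). The postsynaptic scaffold Dlgap1 had 300, 264, 297 and 368 (core frontal to sham 0.716 [0.612–0.836]) and Hnrnpu, a nuclear RNA-binding protein, 256, 184, 258 and 319 (0.704 [0.595–0.833]). In core occipital against sham, Snhg14, a long noncoding RNA of an imprinted locus with 142 circRNAs, was higher (175 and 137, 1.64 [1.30–2.06]), while Ptk2 (367 and 673, 0.699 [0.614–0.795]), the integrin Itga8 (3 and 37, 0.104 [0.0205–0.328]) and the ubiquitin ligase Ubr1 (3 and 29, 0.133 [0.0259–0.428]) were lower. The sodium channel Scn1a had 33, 14, 6 and 20 (penumbra to core frontal 0.229 [0.0785–0.554]) and the transcription factor Yy1 3, 4, 19 and 4 (7.98 [2.35–42.1]).

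The junctions at Gm47283 on chromosome Y, 2 in all, had 16, 24, 56 and 8 counts (132, 289, 581 and 75.1 CPM), lowest in sham. Their ratio to sham was 7.74 [3.67–18.8] in penumbra and 3.85 [1.67–9.91] in core occipital, so the difference from sham is not particular to the penumbra. A larger share of RNA from males in the penumbra pool might raise these junctions, but the other 28 chromosome Y circRNAs together had 58 counts in penumbra and 66 in sham, 0.972 [0.671–1.40], which does not bear that out. A copy number of the locus in the occluded mice would give the same level in penumbra and the cores, if these came from the same mice. The ratio of penumbra to the sum of both cores was 2.97 [1.95–4.58] (56 and 40 counts). The junctions were noticed because they were highest in penumbra, which fixes that ratio in part, so copy number stays open. Reads shared with a near-identical copy on X remain possible, and neither that nor a biological explanation was tested.

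The junctions in Snora61 (39, 3, 1 and 17 counts) and Snord118 (19, 3, 0 and 7) had a joint ratio of penumbra to core frontal of 0.0217 [0.000541–0.126]. All 35 junctions in small or ribosomal RNA genes had 1194, 505, 550 and 798 CPM, so a high core frontal library describes this as well as a low penumbra, and core occipital was as low. A different yield of small structured RNAs between these libraries might account for it and stays open: the other 33 junctions had 52 and 87 counts, 0.753 [0.524–1.07], but that sum decides nothing, although its interval met the bound set beforehand, since its members go both ways (Snora24 12, 0, 0 and 5 counts, Snora34 11, 0, 0 and 2, Snord22 3, 3, 13 and 1). The junction in Snora61 spans that gene from end to end and may not be a circRNA, and no biological explanation was tested.

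The log2 ratios of the occlusion libraries against the shared sham library had correlations of 0.566, 0.583 and 0.651, where simulated libraries without any difference gave 0.535, 0.567 and 0.517, and covariances of 0.450, 0.457 and 0.496 beside 0.237, 0.250 and 0.235. The sham library cannot be split, so its own deviation was not separated from differences that the occlusion libraries share.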
